A study of Mus musculus with 154 samples.

How the data were processed

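Single cells of mouse embryos were sequenced by MARS-seq, a 3' tag method in which cells are sorted one per well into barcoded 384-well plates and transcripts are counted by unique molecular identifiers (UMIs). The series holds 154 plates. Of these, 116 carry wild-type embryos, 79 of C57BL/6 and 37 of the outbred ICR stock. The other 38 carry embryos made from injected mouse embryonic stem cells of the V6.5 line, either carrying the Foxc1/2 double knockout (DKO) or without it (control). In the chimera assay the cells were injected into BDF1 host blastocysts, so that host and injected cells share an embryo. In the tetraploid complementation assay the host was made tetraploid, and the embryo proper is then mostly formed by the injected cells. Chimera plates number 13 for DKO and 8 for control, tetraploid plates 8 and 8, and 1 further tetraploid plate holds an embryo of each kind.

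The deposited values are raw UMI counts per gene and well, with no normalization, in 27400 gene rows, of which 92 are ERCC spike-ins. The 27308 other rows were used. Per the submitters' processing notes, the tools were bcl2fastq 2.15.0.4 and Bowtie2 and the genome build was mm9; the annotation, the UMI filters and the counting program are not given in the sources used here. The authors also deposited tables that list for each well the plate, the embryo and, for wild-type cells, a metacell (a group of like cells) and a developmental time per embryo in embryonic days. For injected embryos the deposited fluorescence intensity of each cell in the sorter was used on a log10 scale. The deposited tables were used for no cell type names and no injected or host calls; both were rebuilt as described next. The replicate is the embryo throughout, and cells were never treated as replicates.

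Wells listed as cells with at least 1000 UMIs were counted as cells. Wild-type cells were clustered without Foxc1, Foxc2, cell cycle, ribosomal and mitochondrial genes. The clustering used 2000 variable genes, 40 principal components, 20 neighbours per cell with 10 from each strain, and Leiden communities (igraph 0.11.9) at a resolution of 1.6, which gave 32 clusters. The resolution and the balancing of strains were set after looking at the clusters and before any test. A cluster took the name of the marker list with the highest mean log2 ratio against the other cells if at least 3 markers were over 1 on that scale and if at least as many of its markers as of any other list stood among its 10 leading genes. The other clusters keep a number. Cluster 5 is led by Foxb1, Cxcl12 and Sox3, cluster 9 by Alx1, Tcf15, Foxc2 and Twist1, cluster 22 by Isl1, Phlda2, Evx1 and Mesp1, and cluster 30 by Prap1 and Prl8a2. Clusters 30 and 32 were left without a name after their leading genes were read by eye. Of 142 marker symbols 141 matched a row, older gene names included, and of 255 gene list symbols 254 matched. Cells of injected embryos took the type held by most of their nearest wild-type cells. The median share of neighbours that voted for it was 0.9 in DKO chimeras, 1 in control chimeras, 0.9 and 0.95 on the DKO and control tetraploid plates and 0.775 on the mixed plate. No doublet caller was run, since each well took 1 sorted cell, and rare doubly filled wells remain.

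Shares are percentages of the counted cells of an embryo that belong to embryonic types. Extraembryonic ectoderm, visceral endoderm and parietal endoderm were left out because a tetraploid host gives them. Clusters of which under 50% of the cells had a deposited metacell were left out too, a rule set after seeing the data. Cluster 24, which kept a number but has visceral endoderm as its best list, was left out with visceral endoderm. The numbered clusters left out held small shares of the cells: cluster 24 held 0.0893% in DKO chimeras, 0% in control chimeras, 0.351% in DKO and 0% in control tetraploid plates, cluster 28 held 0.0351% in DKO tetraploid plates and 0% in the other 3 groups, cluster 31 held 0.0893%, 0.791%, 0.211% and 0.106% in the same order, and cluster 32 held 1.04% in control chimeras and 0% in the other 3.

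In chimeras a cell was called injected when its fluorescence was above the lowest point between the modes of the log10 values of all chimera cells, 2.73. Of 7222 cells, 422 lay within 0.1 of that point. The groups' own lowest points were 2.66 in DKO and 3.09 in control chimeras. Extraembryonic types, which injected cells rarely form, lay above the pooled gate in 1.31% of cells in DKO chimeras and 44.75% in control chimeras, and above the control group's own gate in 8.01%, so a gate per group was added as an alternative after this was seen. Host and injected cells of an embryo were paired. Their profiles deviated from the group means together, with correlations of 0.312 to 0.563 in DKO and 0.314 to 0.452 in control chimeras, each above the highest with any other embryo. The mixed plate's embryo that also stands on a plate of DKO embryos was taken as DKO and the other as control.

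Shares were compared by exact two-sided permutation tests of embryo labels for the tetraploid groups and for the chimera difference, and by exact two-sided sign flips of the within-embryo difference in chimeras. Wild-type tests used 100000 resamples. An embryo needed 50 counted cells, or 20 on each side in a chimera. Expression was compared with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr) in R 4.3.3, on UMI counts summed per embryo, and adjusted p-values are Benjamini-Hochberg values. The threshold was an adjusted p of 0.05. For chimeras the larger side of each embryo and type was drawn down to the smaller, so that host and injected sums hold the same types, and the embryo was a block. Within cell types, an embryo entered with at least 20 cells of the type and a type with at least 3 such embryos in each group. Strain was compared over 68 embryos of 5 age groups of 0.2 days that hold both strains, and for expression with a natural spline of 3 degrees of freedom of the deposited time. A projected time for injected embryos is the mean deposited time of the nearest wild-type cells.

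The 17 gene lists, 22 marker lists, tests, thresholds, groups and most alternatives were fixed before the data were examined. The lists cover somitogenesis and paraxial mesoderm, cardiac and pharyngeal mesoderm, extraembryonic mesoderm and BMP pathway, haematoendothelial genes, epiblast and pluripotency, primitive streak and early mesoderm, neural and ectoderm, definitive endoderm and node, retinoic acid pathway, anterior-posterior Hox and Cdx, cell cycle, early response and stress, hypoxia and glycolysis, p53 targets, imprinted genes, extraembryonic ectoderm and visceral endoderm. Lists were tested with camera and fry (limma 3.58.1), camera once with a preset correlation of 0.01 and once with an estimated one. List calls in the results are those of camera, and fry is not reported. The list tests ran on edgeR's z-scores. Voom weights had been tried first, and values with an estimated correlation then moved with the numerical library in use. With the preset correlation, 34 list tests passed with z-scores and 33 with voom weights of 92, and 7 passed with only one of them. The named genes are Foxc1 and Foxc2, then in each comparison the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 20 CPM (UMIs of a gene per 1e+06 UMIs of the sum, computed here), then up to 4 members with the lowest adjusted p of each list with at least 2 past it, and within cell types the 3 highest and 3 lowest. Genes named outside that rule are said to be so.

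The tests were run on simulated data first. With 200 genes changed in sums like the real ones, edgeR recovered 86% of genes changed by 1 on the log2 scale and 100% of those changed by 2 in the tetraploid comparison (11000 genes), 74.5% and 99% in allantois-like cells (7254 genes), 54.1% and 99% in haematoendothelial-like cells (5369 genes), 93.9% and 99.0% in DKO chimeras (9469 genes), 84% and 100% in control chimeras (9869 genes) and 71.7% and 90.9% for the chimera difference (9906 genes). In both wild-type comparisons all were recovered, over 6041 genes for epiblast and 10602 for strain. Between 2.46% and 6.10% of called genes were false in these simulations. The simulated sums held no effect of sorting day, stage or cell type composition. These rates therefore do not cover real differences that go with a group for such reasons. With no difference, 4.1% of exact label permutations, 3.9% of sign flips, 7% of rank correlations and 6.67% of tests within age groups gave a p under 0.05.

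Alternatives covered minimum UMIs of 2000 and 500, the denominator, a centred log ratio with 0.5 added, cell minima, DESeq2 1.42.0 size factors and its Wald test, no low count filter, all embryonic cells in place of matched ones, another draw, thinning, the embryo block, the mixed plate, a projected time covariate, each strain alone and, for groups of at most 5 embryos, each embryo left out in turn. Added after the data were seen were the gate per group, age groups from another start and leaving out 2 runs of neighbouring genes. Also added then was the log2 total UMIs as a covariate of the tetraploid fits (edgeR over the same genes, least squares for shares). Neighbouring genes were ordered by the GRCm38.p6 gene table, a build other than that of the counts, so no coordinates are given. Intervals, floors of 3 counts and percentages of cells cover counting error only. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.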

Results

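Transcripts were counted in single cells of whole mouse embryos whose embryo of origin was recorded at sorting, in 2 settings. The first is a time course of wild-type embryos, 153 of them (42 ICR, the others C57BL/6) with a deposited developmental time between 6.42 and 8.13 embryonic days. The second follows cells that lack the forkhead transcription factors Foxc1 and Foxc2, known regulators of paraxial and cardiac mesoderm, in chimeras and in tetraploid complementation embryos collected at about E7.5. The question in the second is what these genes do while mesoderm is specified. After filtering, the chimeras gave 4481 cells of 7 DKO embryos (median 3967 UMIs per cell) and 2782 cells of 4 control embryos (7027). The tetraploid assay gave 2891 cells of 5 DKO embryos (5373) and 3108 cells of 5 control embryos (6621.5). Wild-type cells numbered 25428 from C57BL/6 embryos (5150) and 12833 from 42 ICR embryos (3572). Plate totals ran from 727293 to 3000547 UMIs in DKO chimeras, 2027227 to 2875380 in control chimeras, 303939 to 2869386 in DKO and 1634541 to 3009783 in control tetraploid plates, 513291 to 3552465 for C57BL/6 and 867202 to 1880291 for ICR.

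Foxc2 was low in every tetraploid DKO embryo. Its level was 0, 0.699, 17.97, 3.94 and 7.55 CPM in DKO embryos 1 to 5 and 75.7, 54.5, 53.4, 66.2 and 52.6 CPM in control embryos 1 to 5, which fell by 2.89 on the log2 scale (SE 0.430, edgeR adjusted p = 0.000975). Foxc1 was 35.4 ± 14.5 CPM (SD, n = 5) in DKO and 47.2 ± 6.69 CPM (n = 5) in control embryos, a log2 difference of -0.34 that did not pass (SE 0.216, edgeR adjusted p = 0.267). Both genes were read here in sums over all embryonic types. The shares of types differed between the tetraploid groups, so composition can enter both differences. In DKO chimeras Foxc2 was lower in injected than in host cells of 6 of 7 embryos, 41.3 ± 21.6 against 69.96 ± 20.4 CPM (log2 fold change -0.93, SE 0.169, edgeR adjusted p = 0.000185). Embryo 5 was the exception, with 88.0 CPM in injected cells from 31 UMIs against 49.2 CPM in host cells. Foxc1 was higher in the injected cells, 99.4 ± 40.6 against 74.5 ± 28.03 CPM (log2 fold change 0.40, SE 0.0996, edgeR adjusted p = 0.0059). In control chimeras Foxc1 was 49.7 ± 8.63 CPM in injected and 49.9 ± 10.7 CPM in host cells (n = 4, log2 fold change 0.01, edgeR adjusted p = 0.978), a value whose sign turned in 6 alternatives. Foxc2 there was 67.2 ± 17.7 against 47.3 ± 15.5 CPM (0.52, SE 0.141, edgeR adjusted p = 0.022). With the fluorescence gate per group it was at 0.35 and did not pass (edgeR adjusted p = 0.290). The labels do not say which part of either gene was removed, and a 3' tag outside that part checks nothing, so a level that remains does not go against the labels.

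**Figure D1:**
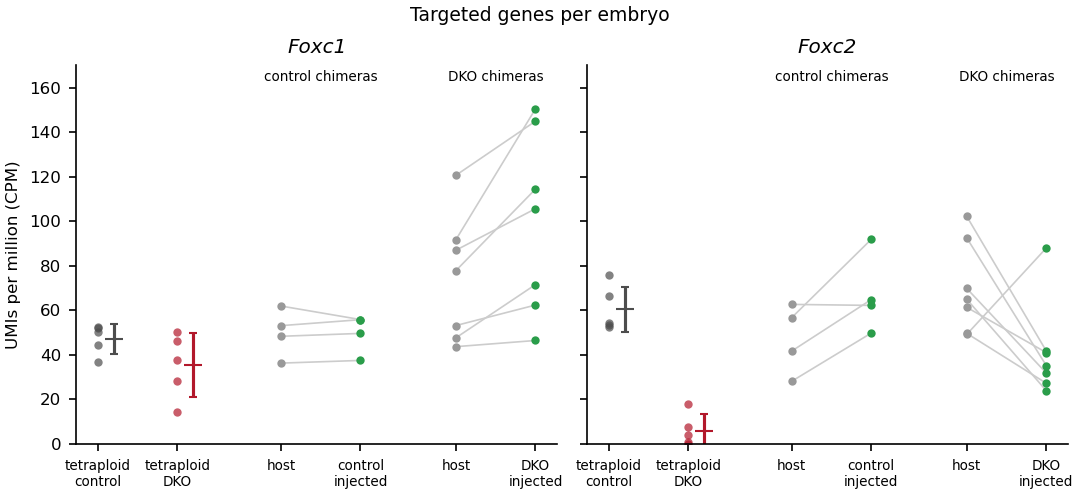
Foxc1 and Foxc2 in CPM (y axis) for each injected embryo, 1 point per embryo, with the mean and SD beside the tetraploid groups and lines that join host and injected cells of a chimera. Foxc2 in tetraploid DKO embryos lies between 0 and 17.97 CPM against 52.6 to 75.7 CPM in their controls.

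Tetraploid DKO embryos held early types where controls held later ones. Epiblast-like cells made up 36.5% ± 30.8 (SD, n = 5) of the DKO embryos and 0.783% ± 1.43 (n = 5) of the controls, and primitive streak-like cells 16.7% ± 6.58 against 0.148% ± 0.33. Cardiomyocyte-like cells made up 11.1% ± 3.11 of control embryos and none of the 2709 embryonic DKO cells, which allows a share of up to 0.111%. Presomitic or caudal mesoderm-like cells were 0.394% ± 0.802 against 9.93% ± 2.57, extraembryonic mesoderm-like cells 2.39% ± 2.79 against 14% ± 1.82, rostral neural plate-like cells 0.119% ± 0.122 against 10.8% ± 5.61 and caudal neural plate-like cells 0.422% ± 0.944 against 7.98% ± 2.22. In each of these 7 types all 5 DKO embryos lay beyond all 5 controls (exact permutation p = 0.00794, the smallest of 252 assignments, adjusted p = 0.0215). Blood-like cells (1.16% against 9.19%), definitive endoderm-like cells (0.855% against 4.77%) and surface ectoderm-like cells (0.803% against 3.72%) were lower in DKO embryos too, with 4 of 5 beyond all controls (exact permutation p = 0.0159, adjusted p = 0.0302).

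Of 19 types, 10 passed, 2 higher and 8 lower in DKO embryos. As a centred log ratio 11 passed, 5 of them higher and 8 of them among the 10; blood-like and surface ectoderm-like cells were lost. Nascent mesoderm-like cells made up 21.5% ± 13.3 of DKO and 0.0738% ± 0.165 of control embryos and did not pass after adjustment (exact permutation p = 0.0476, adjusted p = 0.0823). Among the others that did not pass, allantois-like cells were 8.09% ± 9.23 against 11.7% ± 2.29 (adjusted p = 0.470 by exact permutation), haematoendothelial-like cells 2.28% ± 2.11 against 4.76% ± 2.17 (0.174) and anterior primitive streak-like cells 4.52% ± 5.12 against 0.858% ± 1.59 (0.151). Some classes drew on different clusters. The epiblast-like cells of DKO embryos came from clusters 19 (54.1%) and 1 (34.6%). The presomitic-like cells were of cluster 6 in 78.5% of control cells and all of cluster 8 in the 20 DKO cells, and the caudal neural plate-like cells of cluster 15 in 82.3% of control cells and of cluster 20 in 90.9% of the 22 DKO cells. No type passed without the mixed plate's pair of embryos, where 9 of the 10 had an exact permutation p of 0.0286, the smallest that 4 against 4 can give. Their differences were about as large, such as 33.9 percentage points for epiblast-like cells (35.7 with all embryos), -11.6 for cardiomyocyte-like cells (-11.1) and -12.3 for rostral neural plate-like cells (-10.7). The exception was definitive endoderm-like cells, at -2.68 (-3.91 with all embryos, exact permutation p = 0.0571 without the pair). Without control embryo 2, 6 types passed. With a projected embryo time as covariate no type passed either.

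**Figure D2:**
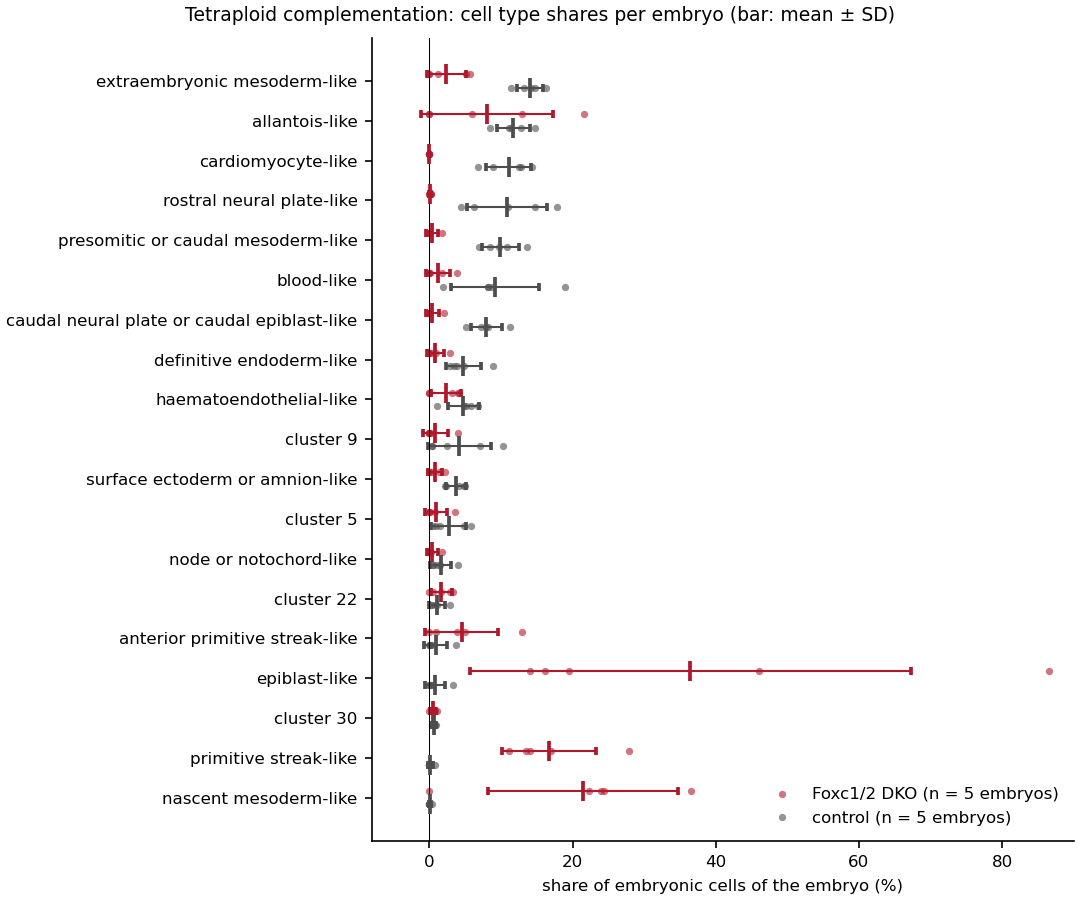
Share of each embryonic cell type in percent (axis) for the 5 DKO and 5 control tetraploid embryos, 1 point per embryo with the mean and SD. Epiblast-like and primitive streak-like cells lie higher in all 5 DKO embryos, and cardiomyocyte-like cells are at 0 in each of them against 11.1% ± 3.11 in controls.

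Transcripts of whole tetraploid embryos followed the same types. The Nodal co-receptor Tdgf1 was at 511 ± 227 CPM in DKO and 3.84 ± 6.34 CPM in control embryos (n = 5 each, log2 fold change 7.801, SE 0.661), the streak regulator Eomes at 329 ± 164.9 against 5.71 ± 5.17 CPM (6.16, SE 0.505), the epiblast growth factor Fgf5 at 170 ± 91.2 against 6.29 ± 4.81 CPM (4.98, SE 0.564) and the metallothionein Mt2 rose by 4.04 (SE 0.779). The retinoic acid synthesis enzyme Aldh1a2 fell from 103.1 ± 38.4 to 1.51 ± 0.645 CPM (log2 fold change -5.90, SE 0.378). Arginase Arg1 fell from 53.4 ± 29.9 to 0.249 ± 0.354 CPM (-7.08, SE 0.719), the embryonic globin Hbb-bh1 from 2169 ± 3510 to 15.2 ± 27.2 CPM (-6.86, SE 1.44), and the axial patterning genes Cdx1 (-3.82, SE 0.521) and Hoxa1 (-3.57, SE 0.408) fell too. The edgeR adjusted p of these genes lay between 8.78e-06 for Aldh1a2 and 0.00612 for Hbb-bh1. In all, 2438 of 11129 genes passed, 1104 higher and 1334 lower, in sums of 1036304 to 6010373 UMIs. Leaving out control embryo 4 or 5 gave 1578 or 1489 genes. With the projected time as covariate 14 genes passed, and 25 of 56 named genes changed sign, Foxc1, Mt2 and Hbb-bh1 among them.

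Gene lists shifted with the same split. Several of them, such as those of epiblast and streak genes, share members with the markers that named the types. The sums hold the same cells and were not matched for type. These shifts therefore follow in part from the shares and are no separate support for them. Of 12 epiblast and pluripotency genes measured, 9 rose and none fell (10 passed adjusted over the list alone), with Utf1 at 5.24, L1td1 at 3.68 and Pim2 at 2.53. Of 18 primitive streak and early mesoderm genes 10 rose (14 over the list alone), with Nodal at 5.17, Lefty2 at 4.57 and Wnt3 at 3.65. Falling members numbered 10 of 12 in the Hox and Cdx list (11 over the list alone), 9 of 15 in the cardiac list (10), with Smarcd3 at -2.49 and Isl1 at -2.04, 8 of 11 in the retinoic acid list (9), with Crabp2 at -2.77, 7 of 15 in the haematoendothelial list (9), with Gata1 at -2.38 and Tal1 at -1.62, and 6 of 19 in the extraembryonic mesoderm and BMP list (6), with Pitx1 at -2.50. In the neural list 7 of 10 fell and Zic2 rose (8 over the list alone), and in the somitogenesis list 4 of 10 fell and 1 rose (5). The imprinted genes had 9 of 19 lower and 1 higher (10 over the list alone), with Dlk1 at -2.30 and the growth inhibitor Cdkn1c at -2.11. Of 9 targets of p53 6 rose (7 over the list alone), among them Pmaip1 at 2.59 and Cdkn1a at 1.32.

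All 11 of these lists passed camera with the preset correlation, at adjusted p values between 7.87e-10 and 7.69e-05. Only the retinoic acid list held its call with an estimated correlation (adjusted p = 0.00348). For the others the adjusted p with an estimated correlation was 0.0661 for somitogenesis, cardiac, neural, Hox and imprinted genes, 0.0684 for epiblast, 0.0982 for p53 targets, 0.274 for streak, 0.296 for haematoendothelial and 0.348 for extraembryonic mesoderm genes. The remaining lists did not pass. In the definitive endoderm list 2 of 12 rose and 3 fell (6 adjusted over the list alone, camera adjusted p = 0.0974), in hypoxia and glycolysis 5 of 15 rose and 3 fell (9 over the list alone, 0.195), in visceral endoderm 1 of 7 fell (1, 0.195), and in early response and stress none of 10 and in extraembryonic ectoderm none of 3 passed in edgeR, with none adjusted over the list alone (camera adjusted p = 0.946 and 0.691). In the cell cycle list 1 of 19 rose and 3 fell (4 over the list alone, camera adjusted p = 0.917), with Mki67 at -1.01, a median of 0.05 and a mean of -0.05. Early response genes also had a median of 0.03 above 0 beside a camera direction below it.

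Within cell types, both types that could be tested differed between the tetraploid groups. In allantois-like cells (3 DKO and 5 control embryos, 311 and 356 cells) Upp1 rose by 2.86 (SE 0.317) and the placental gene Asb4 by 2.63 (SE 0.211), while Aldh1a2 fell by 2.86 (SE 0.478, edgeR adjusted p = 0.000343). Eomes had 84 UMIs in DKO and 2 in control cells, a ratio of 63.4 (95% exact interval 17.01 to 532), and the limb and lateral mesoderm gene Prrx1 had 2 against 95, a control to DKO ratio of 31.5 (8.48 to 264). Hbb-bh1 had no UMI in DKO allantois-like cells and was at least 83.9-fold lower there, by the floor of 3 counts over the group. In haematoendothelial-like cells (3 DKO and 4 control embryos, 90 and 157 cells) the stem cell receptor Lgr5 rose by 3.77 (SE 0.614), the mesoderm regulator T by 3.41 (SE 0.313) and Fgf3 by 3.10 (SE 0.368), Sepp1 fell by 4.72 (SE 1.04), and Clu and Foxc2, with no UMI in DKO cells, were at least 13.1-fold and 10.5-fold lower. In all, 408 of 7505 genes passed in allantois-like cells, 131 higher and 277 lower, and 312 of 5623 in haematoendothelial-like cells, 98 higher and 214 lower. The sum of 720 was 330 with DESeq2, and 427, 478, 342 and 376 without control embryo 5 or DKO embryo 3, 4 or 5.

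In chimeras, 3 types differed between DKO injected cells and host cells in the same direction in each of the 7 embryos. Cluster 22, led by Isl1 and Phlda2, held 9.47% ± 5.71 of injected and 3.23% ± 1.42 of host cells, and definitive endoderm-like cells 1.30% ± 1.16 against 6.14% ± 1.64. Cluster 30 held 0.733% ± 0.367 against 0.147% ± 0.266, a rise that control chimeras share (1.03% ± 0.484 against 0.576% ± 0.225, 4 of 4 embryos). For each of the 3 the exact test gave the smallest value it can (exact sign-flip permutation p = 0.0156), yet after adjustment over 17 types none passed (adjusted p = 0.0885). Blood-like cells were 0.801% ± 1.39 of injected and 7.01% ± 5.83 of host cells (5 of 7 embryos, exact permutation p = 0.0625, adjusted p = 0.212), and allantois-like cells 13.99% ± 7.89 against 8.41% ± 2.297 (5 of 7, exact permutation p = 0.156, adjusted p = 0.295).

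In the 4 control chimeras blood-like cells were 2.16% ± 2.05 of injected against 14.6% ± 9.52 of host cells and allantois-like cells 17.4% ± 7.70 against 10.2% ± 4.04, each in 4 of 4 embryos. None of 14 types passed, and none could, since the smallest exact permutation p of 16 sign flips is 0.125. Host cells of the 2 chimera groups also differed in makeup: cardiomyocyte-like cells were 13.8% ± 3.16 of host cells in control chimeras, and cluster 5 held 19.8% ± 7.18 of host cells in DKO against 0.597% ± 1.05 in control chimeras. Presomitic-like cells were of cluster 6 in 94.95% of the cells in control and of cluster 8 in 78.7% in DKO chimeras, caudal neural plate-like cells of cluster 15 in 93.3% and of cluster 20 in 61.2%.

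The injected-minus-host difference was then compared between the chimera groups. It was -4.84 percentage points in DKO and -1.52 in control embryos for definitive endoderm-like cells (difference -3.32, exact permutation p = 0.00606, adjusted p = 0.115), 6.24 and 0.366 for cluster 22 (5.88, exact permutation p = 0.0242, adjusted p = 0.154), -0.513 and -4.62 for cardiomyocyte-like cells (4.11, the same p values) and -4.22 and 3.29 for extraembryonic mesoderm-like cells (-7.51, exact permutation p = 0.0515, adjusted p = 0.245). None of 19 types passed. Cardiomyocyte-like cells were 0.357% of all cells in DKO chimeras, so a fall as large as in control chimeras could not occur there. Primitive streak-like and nascent mesoderm-like cells were absent among 2420 control chimera cells, which allows a share of up to 0.124%.

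**Figure D3:**
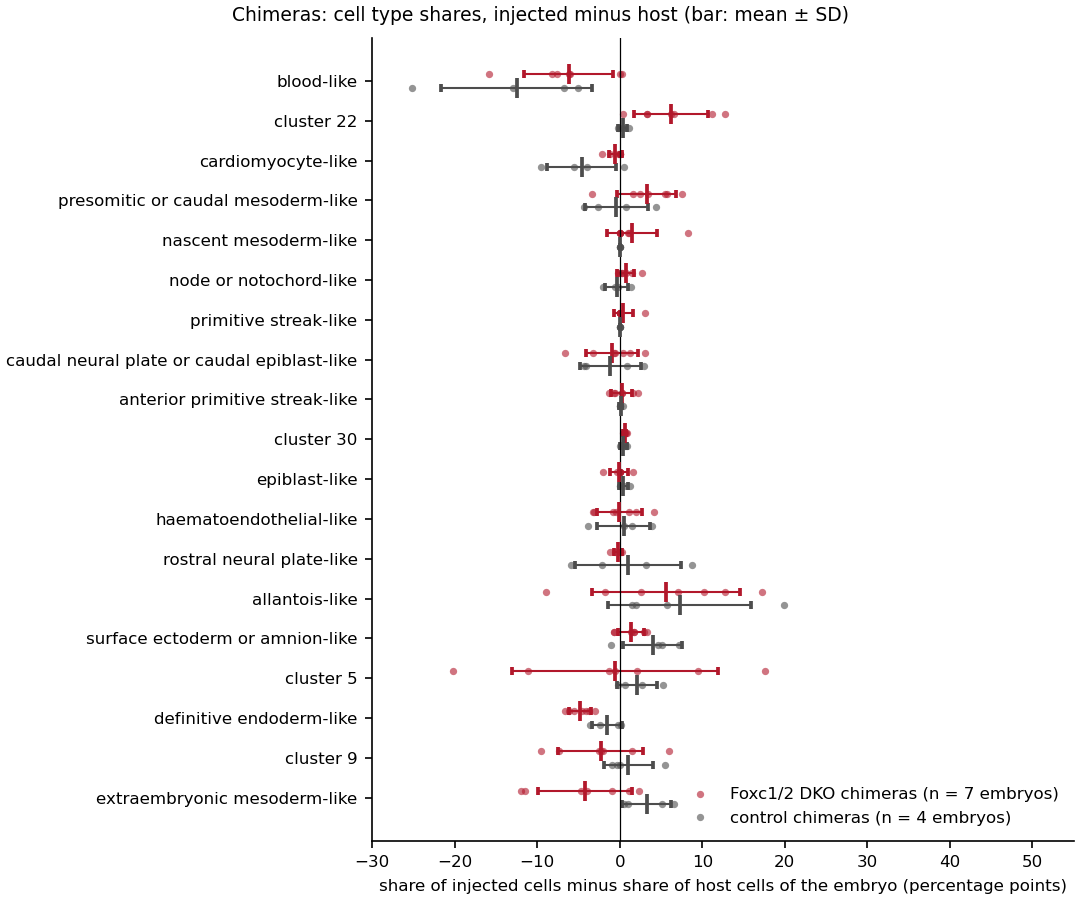
Share of each embryonic cell type in injected cells minus its share in host cells of the same embryo, in percentage points (x axis), for 7 DKO and 4 control chimeras, 1 point per embryo with the mean and SD. Definitive endoderm-like cells lie below 0 and cluster 22 above 0 in all 7 DKO chimeras.

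Between cells of the same embryo matched for type, DKO injected cells had less of the imprinted RNA H19 (113 ± 77.8 against 1463 ± 653 CPM, log2 fold change -3.82, SE 0.192), of the cardiac myosin Myl7 (30.3 ± 10.1 against 102.2 ± 46.6 CPM, -1.67, SE 0.176) and of the presomitic regulator Tbx6 (-0.84, SE 0.130). The X inactivation RNA Xist was lower too (-4.85, SE 0.300), as in control injected cells (-1.92, SE 0.406, edgeR adjusted p = 0.00311). It depends on the sex of host and line. DKO injected cells had more of Mid1 (3.31, SE 0.237), of the metallothioneins Mt2 (120 ± 92.1 against 27.4 ± 10.6 CPM, 2.03, SE 0.154) and Mt1 (1.63, SE 0.169), and of the p53 target Ccng1 (171 ± 61.5 against 62.4 ± 25.02 CPM, 1.45, SE 0.133). Aldh1a2 changed by -0.65 (SE 0.111) and the retinoic acid degrading enzyme Cyp26a1 by -0.71 (SE 0.120). In DKO chimeras the edgeR adjusted p of these genes was at most 8.32e-05. Of 9798 genes 1178 passed, 653 higher and 525 lower, in sums of 352480 to 1489952 UMIs. DESeq2 called 538, a fit without the embryo block 553, and 625 remained without 2 runs of neighbouring genes described further on, 267 of them higher, so without the runs more genes were lower than higher.

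By list, 6 of 8 p53 targets rose in DKO injected cells (6 adjusted over the list alone; camera adjusted p = 3.97e-07, adjusted p = 0.0610 with an estimated correlation), with Trp53inp1 at 0.83 and Cdkn1a at 0.69. In the somitogenesis list 3 of 12 fell (4 over the list alone; camera adjusted p = 0.000805, 0.0937 as the adjusted p with an estimated correlation), in the cardiac list 3 of 14 (3; 0.0237 and 0.0937) and in the retinoic acid list 3 of 11 (3; 0.0382 and 0.116). Glycolysis genes had 5 of 15 lower and 1 higher (7 over the list alone; 0.00175 and 0.0610), with Pkm2 at -0.53 and Tpi1 at -0.44. In the cell cycle list 5 of 19 fell and 1 rose (8; 0.0382 and 0.142), with Top2a at -0.39 and Mcm5 at 0.40. Of 4 visceral endoderm genes 3 fell (3; 0.000122 and 0.0610). Of 19 imprinted genes 6 rose and 5 fell (13 over the list alone; camera adjusted p = 0.641, median 0.09 and mean -0.11), among them Igf2 at 0.43 and Mest at -0.54.

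Control injected cells, which keep both Foxc genes, also differed from their hosts. H19 was at 765 ± 404 against 3457 ± 515 CPM (n = 4, log2 fold change -2.31, SE 0.134), the embryonic globins Hba-x and Hbb-bh1 changed by -2.22 (SE 0.273) and -1.49 (SE 0.240), the tryptophan enzyme Tdo2 by -1.73 (SE 0.210) and the muscle troponin Tnnt2 by -1.31 (SE 0.215), while Mid1 rose by 4.90 (SE 0.284) and Tex15 by 1.75 (SE 0.230), all at an edgeR adjusted p of at most 0.000169. Tbx6 fell here as well, outside the rule for naming genes, by 0.93 (SE 0.132, edgeR adjusted p = 3.86e-05). Of 10101 genes 563 passed, 385 higher and 178 lower. These values use the pooled gate, and 89.5% of the control injected cells lay above that group's own gate. The others may include host cells. With the group's gate H19 changed by -3.57 in place of -2.31, while Foxc2 changed by 0.35 in place of 0.52. In the Hox and Cdx list 3 of 17 fell (3 adjusted over the list alone; camera adjusted p = 0.000563), with Hoxb1 at -0.55, in glycolysis 5 of 15 (6; 0.000541), in imprinted genes 4 of 19 with 1 higher (10; 0.0101), in the retinoic acid list 1 of 11 (1; 0.0269) and in the extraembryonic mesoderm list 2 of 19 (3; 0.0389). Each of these 5 lists had an adjusted p of 0.342 with an estimated correlation, and no p53 target passed (0 of 7 in edgeR, camera adjusted p = 0.724). Counts moved to 185 with DESeq2, 130 without the embryo block, 881 with unmatched cells, 241 without the gene runs (110 higher, so most were lower), and 294 and 310 without control embryo 1 or 3.

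The test of the difference itself gave 75 of 10261 genes, 6 higher and 69 lower in DKO, net of the control line. No chimera plate held embryos of both groups. Their hosts differed too, with the Y-linked Ddx3y and Eif2s3y together at 0.505 CPM in DKO and 53.7 CPM in control host cells. What differs between plates or hosts of the groups can thus enter this test beside the knockout. The paraxial mesoderm regulator Tcf15 was at 3.35 ± 2.75 CPM in DKO injected cells, 31.7 ± 13.9 CPM in their hosts, 41.4 ± 11.5 CPM in control injected cells and 43.1 ± 13.6 CPM in theirs (difference -3.09 on the log2 scale, SE 0.392, edgeR adjusted p = 9.79e-06). The Nodal and BMP antagonist Cer1 differed by -1.93 (SE 0.406), Foxc2 by -1.46 (SE 0.252), H19 by -1.51 (SE 0.306) with the pooled gate, and Ccng1 by 1.08 (SE 0.236) and Mt1 by 1.11 (SE 0.263). Of the 69 lower genes 43 lie in a run of neighbouring genes, such as Tagln2 (-1.29, SE 0.133), Cenpf (-1.27, SE 0.130) and Eprs (-1.21, SE 0.109), while Tcf15, Cer1 and H19 do not. The edgeR adjusted p of the genes named here was at most 0.0285. Without both gene runs 20 genes passed. The count was 39 with DESeq2, 137 without a low count filter (26 higher), 1.2e+02 with unmatched cells (20 higher) and 98 with a fluorescence gate per group (17 higher). With that gate H19 in control injected cells was at -3.57 and its difference at -0.41 (edgeR adjusted p = 0.725), so the H19 difference depends on which control cells are called injected. Tcf15 (-3.54), Cer1 (-2.44), Foxc2 (-1.37), Ccng1 (1.13) and Mt1 (1.06) passed with either gate.

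In camera 5 lists shifted as sets between the groups with either correlation, though at most 1 member of each passed in edgeR. The p53 targets were higher in DKO (1 of 8 passed and 4 adjusted over the list alone, median 0.72, camera adjusted p = 2.42e-05), as was the extraembryonic mesoderm and BMP list (0 of 18 passed in edgeR, 3 over the list alone, median 0.17, 0.0045). Somitogenesis genes were lower (1 of 12, 3 over the list alone, median -0.45, camera adjusted p = 0.00306), as were cardiac genes (1 of 14, 1, median -0.46, 0.00178) and visceral endoderm genes (1 of 9, 2, median -0.73, 1.11e-06). The adjusted p with an estimated correlation was 0.0334 for each of the 5. The calls of 3 further lists were lost with it: cell cycle (0 of 19 in edgeR, 2 over the list alone, 0.00972 against 0.0503), haematoendothelial (0 of 17, 4, 0.00972 against 0.118) and Hox and Cdx (0 of 16, none over the list alone, 0.0326 against 0.191). The retinoic acid list did not pass (0 of 11, 2 over the list alone), and its median of 0.14 and mean of -0.02 differ in sign.

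After these values were seen, genes were set in their chromosomal order, and a pair of runs stood out. The first, from Rxrg to Cr1l, holds 110 genes tested in the chimera difference, among them Tagln2, Cenpf and Eprs, and the mesoderm gene Mixl1. Over its genes tested in each comparison the median log2 fold change was -0.86 in DKO injected against host cells, with 78 genes past the threshold and lower, 0.03 in control injected cells and -0.98 in tetraploid DKO against control embryos. It scored -32.0 against at most 7.98 in 200 shuffled orders, and it holds 43 of the 73 placed genes of the chimera difference. The second spans nearly all of the chromosome that carries Mcm5, Hmox1 and Foxc2, 543 genes tested in control chimeras, from Efnb2 to Itgb1, with a score of 46.1 against at most 8.35. Its median was 0.50 in DKO and 0.46 in control injected cells against hosts, and 0.02 in tetraploid embryos. Of its genes, 318 of 541 in DKO and 248 of 543 in control chimeras passed and were higher, Mt1, Mt2, Tex15 and Mcm5 among them.

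**Figure D4:**
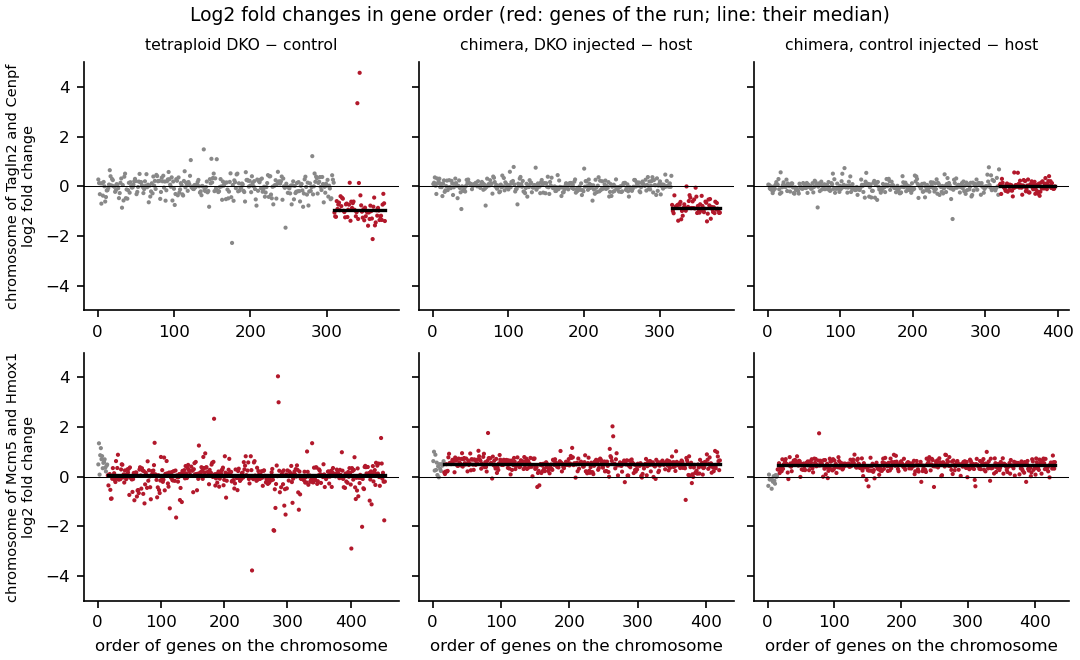
Log2 fold change (y axis) of genes with a mean of at least 20 CPM in their order along the chromosomes of the first and second gene run (x axis), in tetraploid embryos, DKO chimeras and control chimeras; genes of the run are red and the line is their median. Over all tested genes the first run has a median of -0.98, -0.86 and 0.03 in this order and the second 0.02, 0.50 and 0.46.

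Among wild-type embryos, the shares of 17 of 19 types were correlated with deposited time (117 embryos with at least 50 counted cells). How that time was obtained is not given in the sources used here; if it was read from the same cells, these correlations are in part circular. Epiblast-like cells fell from 69.6% ± 15.0 before day 7 (n = 39) to 0.121% ± 0.358 after day 7.8 (n = 25; Spearman rho -0.962, Pearson r -0.936, r -0.938 without the 2 farthest embryos) and primitive streak-like cells from 23.96% ± 11.3 to 0.00606% ± 0.0303 (rho -0.804, r -0.777, r -0.773 without the 2 farthest). Presomitic or caudal mesoderm-like cells rose to 19.8% ± 4.39 (rho 0.854, r 0.837, r 0.831 without the 2 farthest), caudal neural plate-like cells to 12.3% ± 5.0 (rho 0.872, r 0.824, r 0.840), cardiomyocyte-like cells to 11.04% ± 6.87 (rho 0.691, r 0.635, r 0.611) and allantois-like cells to 9.58% ± 3.41 (rho 0.878, r 0.825, r 0.822), each from a mean of 0 before day 7. For these 6 types each permutation p, of rho and of r, was 1e-05, the smallest that 100000 resamples can give (adjusted p = 1.12e-05 for rho). As a centred log ratio, 14 types passed, 12 of them among the 17, and rho of cardiomyocyte-like cells turned to -0.0688, as did the sign of rostral neural plate-like cells and of clusters 5, 9, 22 and 30. Anterior primitive streak-like cells (rho 0.0821, permutation p = 0.378; r -0.0238, p = 0.797, r -0.00349 without the 2 farthest) and nascent mesoderm-like cells (rho -0.170, permutation p = 0.0673; r -0.165, p = 0.0750, r -0.146 without the 2 farthest) did not pass; both had their highest mean from 7.15 days, 9.55% and 38.9%.

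Within strains, rho for epiblast-like cells was -0.959 in C57BL/6 and -0.946 in ICR embryos, for primitive streak-like cells -0.672 and -0.922, for presomitic-like cells 0.796 and 0.909, for caudal neural plate-like cells 0.809 and 0.781, for cardiomyocyte-like cells 0.638 and 0.798 and for allantois-like cells 0.881 and 0.552. The strains cover different times: 48 of the 85 C57BL/6 embryos and 1 of the 32 ICR embryos lay before 7.15 days. Types that peak or level off after that can differ in rho for this reason alone, and the difference between strains was not tested. This holds for anterior primitive streak-like cells (0.305 and -0.761), nascent mesoderm-like cells (0.0424 and -0.814) and clusters 22 (0.611 and -0.0387), 30 (0.578 and -0.0337), 5 (0.552 and 0.197) and 9 (0.541 and 0.259). The epiblast-like cells were of cluster 1 in 92.3% of ICR cells and of clusters 1, 11 and 19 in 42.7%, 36.7% and 20.7% of C57BL/6 cells.

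**Figure D5:**
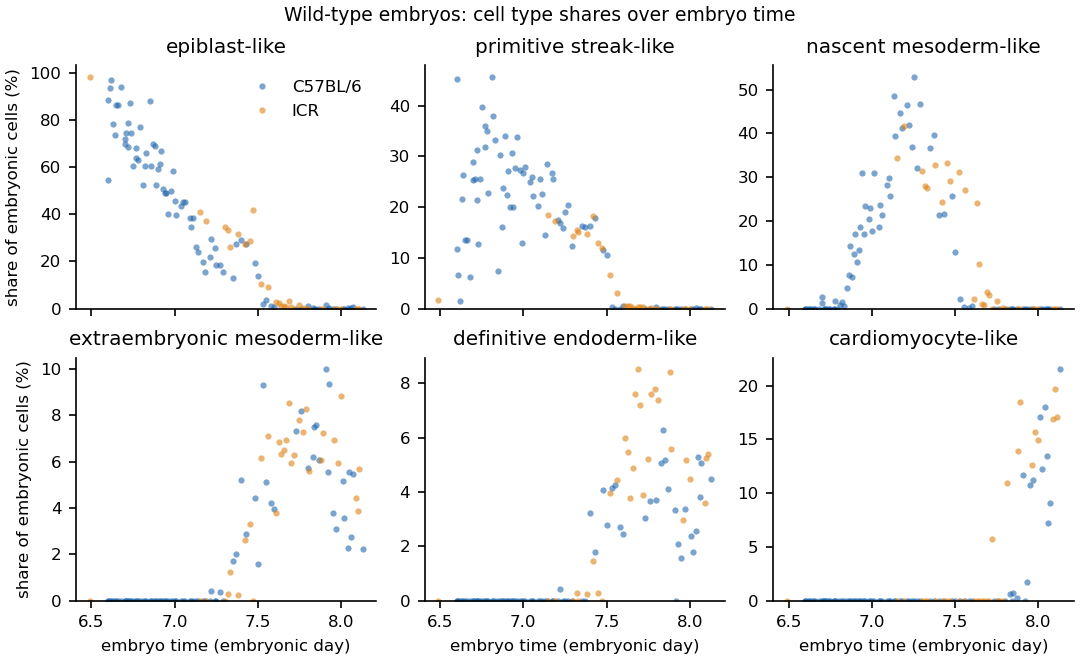
Shares of 6 cell types in percent of embryonic cells (y axis) against deposited developmental time in embryonic days (x axis), 1 point per wild-type embryo, coloured by strain. Epiblast-like cells fall from 69.6% ± 15.0 before day 7 to 0.121% ± 0.358 after day 7.8, while cardiomyocyte-like cells reach 11.04% ± 6.87.

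Epiblast-like cells themselves changed with time over 96 embryos. Per day, the pluripotency gene Dppa4 changed by -7.15 on the log2 scale (SE 0.439), the growth factor Fgf4 by -3.88 (SE 0.287), the methyltransferase cofactor Dnmt3l by -3.21 (SE 0.321), Tdgf1 by -2.69 (SE 0.149) and Nodal by -1.89 (SE 0.229). The transcription factor Sall3 rose by 2.71 (SE 0.278), the activin antagonist Fst by 1.86 (SE 0.217) and Sox2 by 0.77 (SE 0.139). The edgeR adjusted p of these 8 genes was at most 1.07e-05. Of 6233 genes 1192 passed, 625 higher and 567 lower later on, in sums of 68001 to 755782 UMIs; Foxc1 and Foxc2 were too low to be tested. Of 12 epiblast genes 5 fell and 1 rose (7 adjusted over the list alone; camera adjusted p = 0.000113, and adjusted p = 0.00234 with an estimated correlation). Of 5 p53 targets 2 fell (2 over the list alone; 0.00288, and adjusted p = 0.0925 with an estimated correlation), Ccng1 at -1.24 and Trp53inp1 at -1.50. ICR embryos alone gave 377 genes, and embryos with at least 50 epiblast-like cells 516.

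The strains were compared over 37 C57BL/6 and 31 ICR embryos from 7.15 to 8.15 days. ICR embryos had fewer cells of cluster 22, by -2.12 percentage points (5 of 5 age groups, permutation p = 3e-05, adjusted p = 0.00057), and of cluster 5, by -3.96 (4 of 5, adjusted p = 0.0148), and more epiblast-like cells, by 4.78 (3 of 5, adjusted p = 0.0148), and definitive endoderm-like cells, by 1.19 (4 of 5, adjusted p = 0.0171). These 4 of 19 types passed. With a minimum of 2000 UMIs per cell 2 of them passed, both lower in ICR. The permutations moved single embryos within age groups, as if embryos of a sorting day were independent. ICR embryos came from 3 days and C57BL/6 embryos from 8, and no day held both. These p values therefore do not separate strain from day, nor do those for expression below. In expression, the metallothioneins Mt2 and Mt1 were higher in ICR by 2.26 (SE 0.173) and 2.15 (SE 0.164), and the actin regulator Cap1 by 3.07 (SE 0.207). The chaperone Hspa8 was at 1295 ± 544 CPM in C57BL/6 and 11.8 ± 5.31 CPM in ICR (log2 fold change -6.80, SE 0.246), and the ribosomal protein genes Rps18 and Rpl26 changed by -5.89 (SE 0.287) and -5.83 (SE 0.171), all at an edgeR adjusted p of at most 3.54e-18. Foxc1 (0.01, SE 0.111, edgeR adjusted p = 0.930) and Foxc2 (0.12, SE 0.123, 0.430) did not pass.

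By strain 5183 of 10881 genes passed, 2716 higher and 2467 lower in ICR, in sums of 227832 to 9580994 UMIs, and 2923 in a paired fit with 1 value per strain and age group. Glycolysis genes were higher (8 of 15, 9 adjusted over the list alone, camera adjusted p = 0.0235, and adjusted p = 0.750 with an estimated correlation), with Hk2 at 0.65. No other list passed camera with the preset correlation. The Hox and Cdx list had 11 of 16 lower (11 over the list alone, camera adjusted p = 0.0591), with Cdx2 at -0.54, and the p53 targets 4 of 7 (4, 0.0591), with Pmaip1 at -0.70. No sorting day held embryos of both strains, so the count holds what the days of a strain share. With 3 other days of the 11 set against the rest, up to 4972 genes passed where 2 of them were ICR days and up to 4530 where none was. These splits part the strains unevenly too, so strain and day were not separated.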

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

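The tests of the gene runs and of the transcripts that are low in ICR embryos were chosen after those results were seen, as were the fits with the total as a covariate, the splits of sorting days and the distance relative to wild-type embryos; the tests of embryo age by distance, of library size by thinning and of other splits of the embryos were not.

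The effect of injection differed between the chimera groups, by a test of the difference itself, for 75 genes. The paraxial mesoderm regulator Tcf15 had the most negative value among those named, -3.09 on the log2 scale, followed by the Nodal and BMP antagonist Cer1 (-1.93), H19 (-1.51, but -0.41 with a gate per group, edgeR adjusted p = 0.725), Foxc2 (-1.46), Bcap29 (-1.38), Tagln2 (-1.29), Cenpf (-1.27), Gpatch2 (-1.25), Eprs (-1.21) and Mtap1b (-1.21). Fam125b (1.20), Mt1 (1.11), the p53 target Ccng1 (1.08) and Gltp (1.00) were higher in DKO. Tagln2, Cenpf, Gpatch2 and Eprs lie in the first run of neighbouring genes and Foxc2 and Mt1 in the second.

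The first gene run, with Tagln2 and Cenpf, was lower in DKO injected than in host cells of each of 7 chimeras, by a log2 median between -0.92 and -0.72. The run was found between cells matched for type, so that median tests nothing. In tetraploid DKO embryos, which did not define the run, the median was -0.98. There, cell type composition is argued against by a median of -1.01 within allantois-like and -0.90 within haematoendothelial-like cells, and a difference between injected line and host strain by both groups coming from injected lines, with 0.0291 in control injected cells of chimeras. Loss of 1 copy of this stretch in the DKO line is a candidate explanation, and an effect of Foxc1 and Foxc2 on these genes stays open as untested. The second run, with Mcm5 and Mt1, had a median of 0.50 in DKO injected cells as in control injected cells, as an extra copy of that chromosome in both injected lines could give, yet 0.02 between the tetraploid groups, where a copy carried by both would cancel. DNA was not analysed here, so copy number itself was not tested.

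Of 44 groups of 4 to 10 embryos, 7 held an embryo far from the others, and chance gives such an embryo in about 1 in 20 groups. Control tetraploid embryo 1, which was sorted on the mixed plate, held 3.69% anterior primitive streak-like cells (next highest 0.316%), 3.32% epiblast-like cells (0.316%), 0.738% primitive streak-like cells (0%) and 0.369% nascent mesoderm-like cells (0%). Control embryo 1 had 271 counted embryonic cells, and its nascent mesoderm-like share rests on 1 cell. Where the other embryos are at 0, 1 cell can set an embryo apart, so the rate of 1 in 20 does not hold for such shares. DKO tetraploid embryo 3 held 2.11% caudal neural plate-like cells (0%) and 1.82% presomitic or caudal mesoderm-like cells (0.145%). Foxc2 in injected cells of DKO chimera 5 was at 88.0 CPM (next highest 41.8 CPM), from 31 UMIs; no explanation for these embryos was tested.

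The tetraploid DKO embryos held epiblast-like and streak-like cells where controls held cardiomyocyte-like and neural plate-like cells. Embryo age stays open: the mean projected time was 7.23 days in DKO and 7.90 days in control embryos (exact permutation p = 0.00794), and the distance in shares to wild-type embryos of the same projected time gave no decision. It was 19.7 percentage points in DKO and 25.85 in control embryos (difference -6.17, exact permutation p = 0.190), but relative to the median distance among those wild-type embryos it was 1.38 and 1.21 (difference 0.172, exact permutation p = 0.698), and DKO embryo 4 lay beyond the farthest of them, at 29 against 21.85. Projected time is read from the same cells as the shares, so a younger age and a halt of development in the DKO line have not been separated. The first gene run was lower in the same embryos (median log2 fold change -0.98). What its lower transcripts bring about was not separated from the loss of Foxc1 and Foxc2 either. Library size as the whole cause is argued against. Totals overlapped, at 1036304 to 6010373 UMIs in DKO and 1599299 to 5561704 in control embryos. With the log2 total as a covariate 2245 genes passed in edgeR, 2080 of them among the 2438, and the log2 fold changes of the 2438 were a median of 0.914 times their size without it (quartiles 0.848 and 0.976). The group differences of the 10 types that passed were a median of 0.913 times as large (0.831 and 0.967), with epiblast-like cells lowest at 0.687. With each embryo thinned to the lowest total 445 genes passed, under the 50% set as the criterion for library size, but thinning also takes power from the test. The log2 fold changes of the 1979 called genes still tested were then a median of 1.01 times as large (quartiles 0.815 and 1.22). Random thinning leaves the expected fold unchanged, so this ratio says nothing about library size. By the criterion set in advance the thinned count went with library size, and the argument against it rests on the covariate fits alone.

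Transcripts of Hspa8, Rps18, Rpl26 and Vcp were nearly lost in ICR embryos, Vcp at 2.53 to 17.4 CPM against 228 to 588 CPM in C57BL/6 and Hspa8 at 2.32 to 24.3 against 9.39 to 2159 CPM. Embryos of the strains did not overlap for 6 of the 10 transcripts with the most negative values, and did for Hspa8. A batch of single sorting days unrelated to strain is argued against as the whole source. For this, 3 of the 11 days were set against the rest and the 10 lowest transcripts chosen anew. Of 100 splits 1, the real one, had a median log2 fold change as low, -5.70 against -4.54 in the next. The lowest without an ICR day was -4.01. Day medians of the strains lay apart for 9 of the 10 transcripts. Those of C57BL/6 still differed among themselves, with Rps18 at 135.8 to 1681 CPM. For Rpl29 they ran from 9.165 to 435.6 CPM, against 2.12 to 37.98 CPM in ICR. A part played by single days is thus not excluded. A library batch shared by all ICR days and a strain variant against the reference cannot be told apart by strain alone, since no day held both strains. The hosts were BDF1, a cross of strains, and not ICR. If they also carried a variant that caused the loss, they could vary between embryos more widely than clonal injected cells. Whether they carried it was not examined, so their spread cannot decide for or against a variant in ICR. Of the 10, 3 varied over 2 times as widely in hosts of DKO and 4 in hosts of control chimeras, 6 in either group and 1 in both, and 1 varied over 2 times as widely in injected cells. The one in both was Hspa8, at 25.6 to 799 CPM in DKO hosts against 363 to 987 CPM in injected cells of the same embryos, a spread that a batch of embryos or plates would not give to hosts alone. For most of the 10 both groups did not agree, so the shared batch and the variant both stay open.

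Signals also appeared outside the main measurement. Among wells listed as empty, 251 held at least 1000 UMIs, 183 of them on C57BL/6, 26 on DKO chimera, 23 on ICR, 10 on control tetraploid, 7 on DKO tetraploid and 2 on control chimera plates. Cluster 32, led by Spp1, Calcoco2 and Fbxo15 with Dppa3 among its leading genes, held 29 cells in control chimeras, 25 of them in embryo 4, and none of 4481 cells in DKO chimeras, which allows a share of up to 0.0670%. The cells of embryo 4 had a median log10 fluorescence of 4.22, above the 3.55 of injected cells of that group, and 62 of the 63 C57BL/6 cells of the cluster came from 1 embryo; no explanation was tested.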

How the results depend on the processing

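The gate per chimera group, the age groups from another start and the fits without the 2 gene runs were chosen after the data were seen. Beside the counts and leave-one-out values, 2942 values of single types and genes kept their direction and their side of the threshold, 360 kept their direction and no longer passed, 9 came to pass and 51 changed sign. Where no cause is named below, the cause was not tested.

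Tetraploid cell types were sensitive to 3 alternatives. Of 19 types 10 passed. As a centred log ratio 11 did, 8 of them among the 10, with 5 higher in place of 2. None passed without the mixed plate's embryos, where 4 against 4 cannot go below an exact permutation p of 0.0286. The differences stayed about as large for 9 of the 10 (33.9 against 35.7 percentage points for epiblast-like and -11.7 against -11.6 for extraembryonic mesoderm-like cells). Also 0 passed with projected time as a covariate, where epiblast-like cells turned to -38.51 and allantois-like cells to 16.38 percentage points. Leaving out each embryo gave 6 to 10 types. Drawing cells down to the same types in every tetraploid embryo gave no value, since no type was present in all 10.

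With the covariate, 14 of 2438 whole-embryo genes passed, and these turned: Foxc1 0.37, Mt2 -0.43, Hbb-bh1 9.20, Klf1 1.47, Acta2 2.38, Cited4 1.87, Hand2 1.70, Ahnak 1.93, Pitx1 2.19, Gata1 3.03, Tal1 1.73, Irx3 0.24, Crabp1 0.0333, Rbp1 0.46, Hoxb2 1.29, Hoxb1 0.0343, Cenpe 0.0259, Mcm2 -0.10, Slc2a3 0.57, Ccng1 -0.16, Bax -0.17, Cdkn1a -0.62, Snrpn -0.12, Dlk1 0.95 and Igf2r 0.0389. Projected time and genotype nearly coincide, so this fit has little left to estimate either from. Leaving out each embryo gave 1489 to 2878 genes, with 1489 without control embryo 5 and 1578 without control embryo 4. Within cell types the count of 720 was 330 with the DESeq2 Wald test and 342 to 745 with each embryo left out: 427 without control embryo 5, and 478, 342 and 376 without DKO embryos 3, 4 and 5.

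In control chimera shares no type could pass with 4 embryos, where the smallest exact permutation p is 0.125, so the 0 to 0 types with each left out say nothing about stability. In DKO chimera shares and in the difference no type passed under any alternative tried, with 0 to 0 in the difference with control embryos left out. In DKO chimera expression the count of 1178 was 538 with the DESeq2 Wald test, 553 without the embryo block and 625 without the gene runs, which removes tested genes; Mixl1 turned to 0.0370 with all embryonic cells. In control chimeras 563 became 185 with the DESeq2 Wald test, 881 with all embryonic cells, 130 without the embryo block and 241 without the gene runs, and 294 to 565 with each embryo left out (294 without control embryo 1, 310 without control embryo 3). Foxc1 there, near 0, turned to -0.20 with at least 2000 UMIs per cell, -0.18 with all embryonic cells, -0.0185 when thinned and -0.0365 with the gate per group, and with each embryo left out ran from -0.0138 to 0.0746, with -0.00299 and -0.0138 without control embryos 2 and 4; Bmp4 turned to 0.0296 with all embryonic cells. The 75 genes of the difference were 39 with the DESeq2 Wald test, 137 without a low count filter, 1.2e+02 with all embryonic cells, 98 with the gate per group, 20 without the gene runs and 55 to 69 with each control embryo left out.

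Over wild-type time, nascent mesoderm-like cells turned to 0.122 with all counted cells and 0.0424 in C57BL/6 alone. With a centred log ratio these turned: cardiomyocyte-like -0.0688, cluster 22 -0.0567, cluster 30 -0.491, cluster 5 -0.0963, cluster 9 -0.0608, rostral neural plate-like -0.0360 and anterior primitive streak-like -0.397. In ICR alone cluster 22 turned to -0.0387, cluster 30 to -0.0337 and anterior primitive streak-like cells to -0.761. Of the 1192 epiblast genes, 377 passed in ICR alone and 516 with at least 50 epiblast-like cells, both with fewer embryos. The strain comparison gave 2 of 19 types with at least 2000 UMIs per cell and 2923 of 5183 genes when paired by age group. Strain values that turned were Foxc1 at -0.0123 without a low count filter and -0.17 paired, Foxc2 at -0.0868 paired and Mesp1 at -0.00313 without the age covariate.

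The number of cells limits what a share of 0 can exclude: 0 of 2709 DKO tetraploid cells allows up to 0.111% cardiomyocyte-like cells, and Foxc2 rests on 0 to 108 UMIs per DKO tetraploid embryo.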

Other observations

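The tests of other splits of the embryos were planned, while those of whole sorting days were added after the results were seen, and the reading of Tcf15 beside presomitic shares, Tbx6 and Ccng1 and of projected time in chimeras was chosen after the values were seen.

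DKO injected cells in chimeras kept presomitic or caudal mesoderm-like cells, 14.1% ± 3.20 against 10.8% ± 2.88 in host cells (n = 7, exact permutation p = 0.0625). Cluster 9, which has Tcf15 among its leading genes, held 9.94% ± 4.82 of injected and 12.3% ± 4.10 of host cells. It was lower in 5 of 7 embryos (exact permutation p = 0.281). Tcf15 fell by 3.10 on the log2 scale between cells matched for type (edgeR adjusted p = 1.37e-09). Tcf15 was named here after its value was seen, and in control chimeras it fell by 0.02 (edgeR adjusted p = 0.985). Tbx6, a gene of presomitic mesoderm, fell in both groups, by log2 values of -0.84 and -0.93, so its fall is shared with the control line. Ccng1 rose by 1.45 in DKO and 0.37 in control injected cells (edgeR adjusted p = 0.15 in the latter).

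Embryos of the chimera groups differed in projected time. It ran from 7.38 to 7.89 days in the 7 DKO and from 7.92 to 8.01 days in the 4 control chimeras, host cells included, so the difference between the groups also sets embryos of different stages side by side. Within embryos, injected cells were projected earlier than host cells in all 7 DKO chimeras, with differences of -0.104 to -0.0367 days (exact permutation p = 0.0156), and in all 4 control chimeras, with -0.0691 to -0.0232 days (exact permutation p = 0.125). Projected time is read from the same cells, so a stage difference between injected and host cells stays open for each comparison of the 2, also between cells matched for type.

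A chance split of embryos was argued against as the source of most counts of genes, in refits with the embryos split otherwise. Such refits cannot tell genotype from a stage or plates that go with it. The tetraploid whole-embryo count of 2438 was met by 1 of 100 splits, the real one, with 73 as the highest other, and the count within cell types of 720 by 1 of 35, with 1.8e+02 as the highest other. The DKO chimera count of 1178 was met by 1 of 64 (highest other 177), and the chimera difference of 75 by 1 of 100 (8). The strain count of 5183 was met by 1 of 40 splits of embryos (9), but these mix sorting days, and embryos of a day are not independent. With whole days split otherwise it was met by 1 of 100, with 4972 as the highest other. Splits without an ICR day gave up to 4530 genes, and the splits differed in how many embryos stood on each side. Their counts are thus not alike in power, and a chance choice of days is not excluded. For control chimeras, with 563 genes against 0 in the highest other, 8 splits are too few for a share under 0.05.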
